A study of Mus musculus with 19 samples.

How the data were processed

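The series measured RNA in mouse brain after bone marrow transplantation, in 6 hippocampus libraries and 13 libraries of sorted cells. Per the labels, total RNA was isolated with either of a pair of column kits and libraries were made with standard Illumina protocols as stranded RNA. Which kit served which sample is not stated. The deposited values are normalised counts, a signal on a scale with nearly equal library totals, made by the authors with cutadapt 1.9, STAR 2.5.2a and RSEM 1.2.30 on the genome build GRCm38, per the submitters' processing notes, which give neither the role of each tool nor the annotation release. The method that scaled the signal is not stated in the deposited files. Library totals ran from 982114.4 to 1078635.6 in the hippocampus table and from 890564.5 to 1090630.5 in the sorted-cell table.

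In each library most values were whole multiples of a smallest step, taken as the value of 1 read: 82.9% to 83.9% of the values in the hippocampus table and 69.3% to 73.8% in the sorted-cell table, within a tolerance of 0.02 of a step. All values under 100 steps were multiples of a hundredth of that step, within a tolerance of 0.02 of a hundredth, as fractional read counts scaled by a factor per library would be. Whole counts could not be recovered, so a planned test on counts was not run. Dividing the totals by the step gave an estimated 16673616 to 18546936 reads per hippocampus library and 7901523 to 35844769 per sorted library, which set the precision of low values. The tables list 15634 and 13783 genes, a selection by the authors with no stated rule, so genes below their limit were not analysed here. Gene identifiers were matched to symbols, coordinates and GC content in a GENCODE annotation of GRCm38, where 192 and 213 identifiers had no match. Reads shared by near-identical genes, such as H2-Q4, H2-Q6 and H2-Q7, Tgtp1 and Tgtp2, or the guanylate-binding protein family, were divided by the authors' counting, so their separate values are uncertain.

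Groups were taken from the sample titles. Values were transformed as log2 of the value plus 1, and genes with a value of at least 1 in at least 3 libraries were tested, 14404 in hippocampus and 13086 in sorted cells. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The hippocampus model held the groups only. The sorted cells were fitted in 1 model over 13 libraries with the API number of the titles, 183 or 197, as a covariate, since each group held libraries of both. Fold changes are log2 differences from these models, given with their standard errors, and group means and SD are of the deposited values. The comparisons were GVHD against TCD hippocampus, donor macrophages against GVHD host microglia, GVHD against TCD host microglia, and donor macrophages against TCD host microglia.

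The comparisons, the rule for the filter, the alternatives, 49 gene lists and the rule for named genes were fixed before the data were examined. The filter value of 1, and with it the stricter alternative of 5, was settled once the library totals were seen. Lists with at least 5 tested members were compared with the other tested genes by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, which asks whether the genes of a list move one way or in either direction without setting them against other genes. Named genes were, per comparison, the up to 10 with the largest fold change in each direction among called genes with no overlap between the groups, passing over predicted genes, up to 4 members with the smallest p of each list described, and fixed genes of MHC class II, microglia and macrophages. Lists described were those called by camera and those of MHC classes, interferon, microglia, macrophages, T cells, neurons, neurogenesis and glucocorticoid response. Other list members are named as examples chosen after their values were seen. The counts adjusted over the list alone use the same model and adjust over the members of 1 list.

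The models were tested on simulated values drawn from the real means and spreads with known changes. Of 100 genes changed 2-fold, 69 were recovered in the hippocampus design, 40 for donor macrophages against GVHD host microglia, 42 for GVHD against TCD host microglia and 47 for donor macrophages against TCD host microglia; of 100 changed 4-fold, 90, 79, 75 and 76 were. Among unchanged genes 9 of 14166, 4 of 12765, 5 of 12751 and 8 of 12778 were called. The simulated genes were drawn independently of each other, with no GC trend between libraries and no library set apart. These rates may therefore not hold for the real libraries.

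Alternatives covered the pseudocount, the filter, rescaling, quantile normalisation, the variance trend, a minimum fold change, leaving out each library, the replicate number as a block, the API covariate, the libraries fitted together, array weights, an animal block and the kind of list test. A correction for GC content, Ttr as a covariate in hippocampus and a fit without the 3 sorted libraries with the steepest GC trend were added after the data had been seen.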

Results

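RNA was sequenced from mice that had received a bone marrow transplant after split-dose total-body irradiation of 1100 cGy. Every recipient was given 5000000 T-cell-depleted (TCD) marrow cells. In the chronic graft-versus-host disease (GVHD) groups 500000 splenic T cells were given with them. Hippocampus was taken on day 80 from 3 GVHD mice and 3 TCD mice. On day 70, cells were sorted from the brain as donor bone marrow-derived macrophages of GVHD mice (6 libraries), host microglia of GVHD mice (4 libraries) and host microglia of TCD mice (3 libraries). TCD host library 1 is TCD by its title, but its description field carries Syn where the other TCD host libraries have TCD. What Syn stands for is not stated, so the transplant group of this library is uncertain. It is also the only TCD host library of the lower API number. The hippocampal libraries held an estimated 16673616 to 18546936 reads assigned to genes and the sorted libraries 7901523 to 35844769. Xist was present in all 19 libraries, and the 4 Y-linked genes looked for were absent from both tables.

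The hippocampus comparison asks what differs in this brain region between mice with chronic GVHD and TCD recipients without it. The clearest difference lay in genes of the choroid plexus, the tissue that makes cerebrospinal fluid. Choroid tissue carried over with the hippocampus and a change in choroid plexus expression could not be told apart as its source. Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321 on GRCm38), which encodes the thyroxine carrier transthyretin, had a normalised value of 2352 ± 1264 against 27.5 ± 27.8 (GVHD against TCD, SD, n = 3 and 3). Its log2 fold change was 6.65 ± 0.70 (SE, adjusted p = 0.0160). Camera also placed lists of interferon response and antigen presentation genes above the other genes, with adjusted p = 0.551 to 0.611 with an estimated correlation, and only 2 of their genes passed over all genes. Neuron and excitatory synapse lists lay slightly below, with adjusted p = 0.551 and 0.621 with an estimated correlation and no member passing over all genes. In all, 46 of 14404 tested genes rose and 23 fell. The groups did not overlap for any of these 69 genes, nor for 24.0% of all tested genes, where chance gives 10%.

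Of the 14 measured members of the list fixed for carry-over of thalamus or choroid plexus, 9 rose and none fell, with a median log2 fold change of 3.01 (camera adjusted p = 9.38e-12, but adjusted p = 0.551 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell. Beside Ttr these included Kcne2 (3.79 ± 0.35, SE), a potassium channel subunit, Clic6 (4.00 ± 0.40), Prlr, the prolactin receptor (3.57 ± 0.30), and Slc4a5, a bicarbonate transporter (3.65 ± 0.42). Folr1, a folate receptor that carries folate into cerebrospinal fluid, rose by 3.36 ± 0.44. Outside the list, F5, coagulation factor V (4.21 ± 0.41), Mfrp (3.76 ± 0.46), Tmem72 (3.41 ± 0.47) and Kcnj13, another potassium channel (3.36 ± 0.36), were among the 10 named genes with the largest rises. The GVHD libraries were not alike in these genes: Ttr stood at 2867, 912 and 3278 in GVHD libraries 1, 2 and 3, and at 59.3, 15.9 and 7.34 in TCD libraries 1, 2 and 3.

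**Figure D1:**
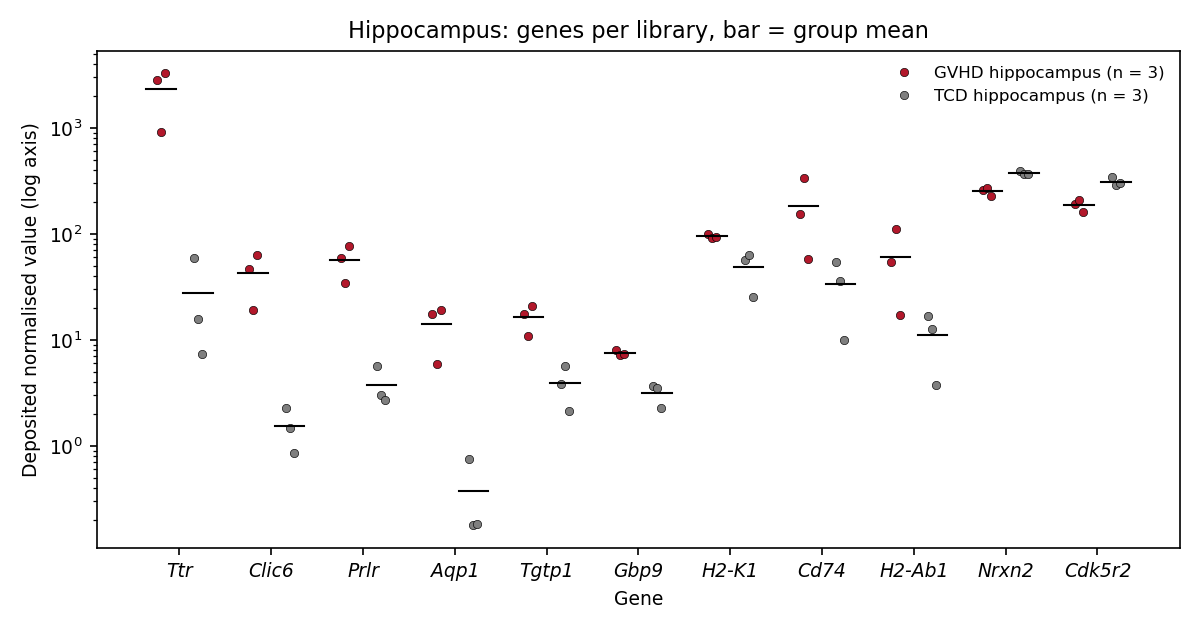
Deposited normalised value (log axis) of 11 genes in each of the 3 GVHD and 3 TCD hippocampus libraries, with a bar at each group mean. GVHD library 2 had the lowest Ttr value of its group (912) and the highest Cd74 value (340.2).

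Among immune genes, 2 of the 18 tested interferon-gamma response genes rose, the GTPase genes Tgtp1 (1.84 ± 0.30, SE, adjusted p = 0.0468) and Gbp9 (1.06 ± 0.17, adjusted p = 0.0454), both of which act against intracellular pathogens. Adjusted over the list alone, 17 rose, and the list had a median log2 fold change of 0.86 (camera adjusted p = 5.53e-12, but adjusted p = 0.551 with an estimated correlation). None of the 17 MHC class I presentation genes rose by limma, where 2449 genes of all kinds had an unadjusted p under 0.05, but 14 rose adjusted over the list alone (median 0.83; camera adjusted p = 1.34e-10, but adjusted p = 0.551 with an estimated correlation). H2-Q7 had a log2 fold change of 1.59, H2-K1 of 1.06 and B2m, the light chain of class I molecules, of 0.92. In the type I interferon list 11 of 20 rose adjusted over the list alone and none over all genes (median 0.53; camera adjusted p = 4.67e-08, but adjusted p = 0.551 with an estimated correlation), with Bst2 at 1.31 and Ifit3 at 1.04.

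The MHC class II list, which presents antigen to CD4 T cells, had a median log2 fold change of 1.70 over 8 genes (camera adjusted p = 3.76e-04, but adjusted p = 0.611 with an estimated correlation), and 6 rose adjusted over the list alone but none over all genes. Cd74, the invariant chain, had values of 185 ± 143 against 33.3 ± 22.2 (SD, n = 3 and 3) and a log2 fold change of 2.38 ± 0.69 (SE, adjusted p = 0.149). H2-Ab1 (2.21 ± 0.66), H2-Aa (2.17 ± 0.73), H2-Eb1 (1.98 ± 0.67) and Ciita, the class II transactivator (0.93 ± 0.26), did not pass the test either. Cd74 was highest in GVHD library 2 (340.2), the GVHD library with the lowest Ttr value, and lower in libraries 1 (156) and 3 (58.5).

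Further lists of immune and glial genes lay above the other genes by camera, each called with the preset correlation alone. These were complement (median 0.47, adjusted p = 0.551 with an estimated correlation, C3 at 1.45), lysosome and cathepsins (0.18, 0.551, Ctss at 0.65), disease-associated microglia (0.27, 0.611, Cd63 at 0.52) and NF-kB targets (0.25, 0.551, Tnfaip2 at 0.93). Monocyte genes had a median of 0.47 (adjusted p = 0.551 with an estimated correlation), and 1 of 5 rose: Ace, the angiotensin-converting enzyme, which choroid plexus also makes (1.93 ± 0.29, SE). The brain-engrafted macrophage list had a median of 0.41 with Lyz2, lysozyme, at 2.08 ± 0.62 (adjusted p = 0.621 with an estimated correlation for the list). Toll-like and pattern recognition receptors (0.23, Tlr2 at 1.04), Fc receptors (0.21, Fcgr2b at 0.71) and reactive astrocyte genes (0.29, Gfap at 0.30 ± 0.27) were also called upward, at adjusted p = 0.621, 0.632 and 0.621 with an estimated correlation. All 14 myelin genes had positive fold changes (median 0.42; camera adjusted p = 1.70e-06, but adjusted p = 0.621 with an estimated correlation), such as Opalin at 0.74. Aif1 (0.51 ± 0.21) and Cd68 (0.22 ± 0.25), general markers of microglia and macrophages, did not pass the test.

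Neural lists had slightly lower values, by camera with the preset correlation. The neuron list had a median of -0.20 (5 of 16 fell adjusted over the list alone; adjusted p = 0.551 with an estimated correlation) and the excitatory synapse list of -0.14 (6 of 18 fell; adjusted p = 0.621 with an estimated correlation). Examples were Syn1, a synaptic vesicle protein, at -0.35 and Grin1, an NMDA receptor subunit, at -0.43. Astrocyte (-0.13), oligodendrocyte precursor (-0.15) and homeostatic microglia genes (-0.17) were called downward as well, at adjusted p = 0.621, 0.621 and 0.645 with an estimated correlation. Among single genes, Nrxn2, a presynaptic adhesion protein (-0.57 ± 0.08, SE), Cdk5r2, a neuronal activator of the kinase Cdk5 (-0.73 ± 0.11), Map1lc3a, an autophagy protein (-0.68 ± 0.10), and Slc30a3, the vesicular zinc transporter (-0.58 ± 0.09), fell. Nat14 (-0.87 ± 0.14, SE), Tmem158 (-0.83 ± 0.12), Dact3 (-0.72 ± 0.11), Ptms (-0.67 ± 0.11), Rasl10b (-0.62 ± 0.10) and Emc10 (-0.55 ± 0.08) fell too. None of these 10 genes passed after GC correction or with the replicate block: the falls, 23, became 3 after GC correction, 1 with the replicate block and 3 without GVHD library 2. GC slopes were negative in the 3 GVHD libraries (-0.117 to -0.0156) and positive in the 3 TCD libraries (0.0129 to 0.0940). The neurogenesis (-0.09, camera adjusted p = 0.521) and glucocorticoid-responsive lists (camera adjusted p = 0.938) were not called. The T cell list had fewer than 5 tested members, of which Cd8a had a log2 fold change of 1.12 ± 0.25 (adjusted p = 0.0867).

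Camera called 15 lists upward and 5 downward of 43 tested, quantile normalisation left 13 upward and no downward call, and none was called with an estimated correlation or by directional fry. With single libraries left out, the interferon-gamma median ran from 0.505 (without TCD library 3) to 1.06 (without TCD library 2). The MHC class I median ran from 0.476 to 1.06 without the same libraries. That of disease-associated microglia ran from 0.121 (without TCD library 3, call lost) to 0.291 (without GVHD library 3). The count of 69 genes depended on single libraries: limma called 0 without GVHD library 3 (1828 at an unadjusted p under 0.05) or TCD library 2 (1967 unadjusted), 2 without GVHD library 1 and 123 without TCD library 3, and a fit without the variance trend called 0 (2343 unadjusted).

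Donor macrophages and host microglia of GVHD mice were compared to ask how marrow-derived cells that settled in the brain differ from the resident microglia. Donor cells carry the genome of the marrow donor and host cells that of the recipient. A difference of genotype between them would enter every donor against host contrast and was not separated from cell type. Host cells were also in the recipient during the irradiation, and the donor marrow was given after it. Irradiation was therefore not separated from cell type in these contrasts either. Donor and host cells differed in a large share of their transcripts. Donor cells had high values of macrophage and monocyte genes, MHC class II genes and lipid handling genes. The genes that mark resident microglia were far lower. Clec12a, an inhibitory lectin receptor of myeloid cells, had values of 308 ± 65.9 against 5.57 ± 3.11 (SD, n = 6 donor and 4 host libraries), a log2 fold change of 5.67 ± 0.28 (SE). Sall1, a transcription factor that maintains microglial identity, had 9.35 ± 4.31 against 279 ± 15.6 (-4.87 ± 0.30). Limma called 2533 genes higher and 2519 lower of 13086 tested, 1126 and 1007 of them by at least 2-fold.

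All 20 brain-engrafted macrophage genes rose, with a median log2 fold change of 4.12 (camera adjusted p = 3.03e-16, but adjusted p = 0.0607 with an estimated correlation). They included Ms4a7 (5.35 ± 0.32, SE), F13a1, a coagulation factor subunit (5.88 ± 0.69), Klra2 (5.68 ± 0.37), Lyz2 (4.58 ± 0.19) and Apoe, the main lipid carrier of the brain, at 69531 ± 12591 against 3851 ± 1265 (4.24 ± 0.22). All 15 monocyte genes rose (median 3.80; camera adjusted p = 5.69e-07, but adjusted p = 0.556 with an estimated correlation), among them Itgal, an integrin chain of leukocytes (3.80 ± 0.19), and Fn1, fibronectin (4.55 ± 0.53). The genes with the largest rises also held Plbd1 (6.04 ± 0.38), Gdf3 (5.83 ± 0.38), Tlr8, an RNA sensor of endosomes (5.81 ± 0.24), Mgl2, a lectin of alternatively activated macrophages (5.76 ± 0.57), Cd93 (5.72 ± 0.29), Sirpb1c (5.64 ± 0.42) and Gpr141 (5.37 ± 0.72). Of the 20 homeostatic microglia genes 18 fell and none rose (median -2.67; camera adjusted p = 4.60e-14, but adjusted p = 0.0805 with an estimated correlation). P2ry12, the purinergic receptor of surveying microglia, went from 12958 ± 1284 in host cells to 1159 ± 281 in donor cells (-3.56 ± 0.14), Slc2a5, a fructose transporter, changed by -4.73 ± 0.29, and Tmem119 by -1.71 ± 0.18. Sall3 (-4.87), Ccr6 (-5.42), Csmd3 (-5.12), Upk1b (-5.09), Nav3 (-5.02), Ecscr (-4.72), Adamts1 (-4.54) and Sgce (-4.45) were the other genes with the largest falls. Ccr6 was also low in TCD host library 1, which stood apart from the other host libraries.

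Of the 10 MHC class II genes 7 rose and 2 fell (median 2.63; camera adjusted p = 0.00302, but adjusted p = 0.790 with an estimated correlation). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) had values of 19946 ± 4655 against 1718 ± 1067 (SD, n = 6 and 4), a log2 fold change of 3.71 ± 0.33. H2-Aa (3.96 ± 0.33), H2-Eb1 (3.75 ± 0.38), Ciita (3.70 ± 0.18) and Cd74 (3.27 ± 0.30) rose by similar amounts, while H2-Oa (-0.58) and H2-Ob (-0.59), chains of a modulator that restrains peptide loading, fell. In the type I interferon list 14 of 26 rose and 1 fell (median 0.92; camera adjusted p = 6.35e-05, but adjusted p = 0.790 with an estimated correlation), including Bst2, which tethers budding virus (1.67 ± 0.11), and Oasl1 (1.92 ± 0.24). Interferon-gamma response genes (5 of 19 rose, median 0.35) and MHC class I genes (6 of 17 rose and 2 fell, median 0.30) were not called as lists, at camera adjusted p = 0.127 and 0.213. Gbp8 (2.30 ± 0.20), Ifi47 (2.70 ± 0.33) and Tap1, a peptide transporter (1.23 ± 0.16), rose and H2-Q4 fell (-2.34 ± 0.51).

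Lipid handling genes rose in 12 of 16 cases and none fell (median 1.39; camera adjusted p = 2.10e-06, but adjusted p = 0.0607 with an estimated correlation), among them Soat1, which esterifies cholesterol (1.55 ± 0.08), Plin2, a coat protein of lipid droplets (1.82 ± 0.17), and Fabp5, a fatty acid carrier (2.62 ± 0.19). The disease-associated microglia list, 11 up and 4 down of 20 (median 1.08; camera adjusted p = 0.0129, but adjusted p = 0.283 with an estimated correlation), shared Apoe and Fabp5 with these lists, and held Igf1, a growth factor (4.07 ± 0.28), as well as Cd9, a tetraspanin that fell (-1.73 ± 0.12). Of the p53 targets 9 fell and 1 rose of 14 (median -0.71; camera adjusted p = 0.00894, but adjusted p = 0.790 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle (-2.41 ± 0.41), Phlda3, an inhibitor of Akt (-2.16 ± 0.34), and Eda2r (-2.09 ± 0.26) fell, and Plk2 rose (1.36 ± 0.25). Neutrophil genes rose in 8 of 12 cases with 1 fall (median 2.72, camera adjusted p = 0.0104, but adjusted p = 0.790 with an estimated correlation). Some had low values in donor cells, such as 13.3 ± 5.44 for Mmp9 and 8.98 ± 7.03 for Retnlg. Others varied widely between donor libraries, such as Ngp (0.217 to 317) and Ltf (0.325 to 112). The reactive astrocyte list rose in 5 of 10 members (median 0.94; camera adjusted p = 0.0203, but adjusted p = 0.196 with an estimated correlation). Of these Vim, the intermediate filament vimentin (3.50 ± 0.34), and Cd44, a hyaluronan receptor (2.35 ± 0.41), are also made by macrophages. Gfap had a value of 16.3 ± 5.95 in donor cells and 6.01 ± 1.05 in host cells. T cell genes were low in both groups (camera adjusted p = 0.932, 1 of 14 rose, Cd28 by 0.71 ± 0.22). Glucocorticoid-responsive genes, with 3 up and 4 down of 12, were not called by camera (adjusted p = 0.573). Sgk1 fell (-2.35 ± 0.16) and Zbtb16 rose (1.85 ± 0.25). The neuron and neurogenesis lists had fewer than 5 tested members each in sorted cells. Camk2a had a log2 fold change of -0.72 ± 0.18 and Prox1, at 0.325 ± 0.302 in donor and 10.1 ± 3.75 in host cells, of -3.00 ± 0.22.

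The groups did not overlap for 3561 of the called genes, and for 27.9% of all tested genes, where chance gives 0.952%. Camera called 8 lists upward and 2 downward of 39, none of them with an estimated correlation, and directional fry called 21. The labels do not state which donor and host libraries came from 1 mouse. A paired fit that took libraries with equal API and description numbers as 1 animal called 5815 genes, and the title number as a replicate block called 4587.

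Host microglia of GVHD and TCD mice were compared to ask how the resident cells differ in mice with GVHD. GVHD host microglia had higher values of MHC class II genes: H2-Eb1 at 580.2 ± 388 against 63.1 ± 40.5 (SD, n = 4 GVHD and 3 TCD libraries), a log2 fold change of 3.23 ± 0.45 (SE, adjusted p = 0.0134). Also higher was Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) at 6155 ± 3891 against 845 ± 373 (2.82 ± 0.35, adjusted p = 0.00873). Camera called the MHC class I and interferon-gamma lists upward as well, with adjusted p = 0.0345 and 0.0661 with an estimated correlation, and 2 of 17 and 1 of 19 of their genes rose over all genes. Homeostatic microglia genes had a median log2 fold change of -0.16 (adjusted p = 0.533 with an estimated correlation). Limma called 12 genes higher and 2 lower of 13086, with 897 at an unadjusted p under 0.05. The groups did not overlap for any of the 14, nor for 6.55% of all tested genes, where chance gives 5.71%.

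All 10 MHC class II genes had positive fold changes, 5 rose over all genes and 9 rose adjusted over the list alone (median 1.72; camera adjusted p = 2.06e-23, adjusted p = 0.0345 with an estimated correlation). Beside H2-Eb1 and Cd74 these were H2-Aa (2.83 ± 0.39, adjusted p = 0.0134), H2-Ab1 (2.61 ± 0.39, adjusted p = 0.0226) and Ciita (2.02 ± 0.22, adjusted p = 0.00357). H2-Ab1 stood at 1718 ± 1067 in GVHD and 280.1 ± 151 in TCD host microglia, against 19946 ± 4655 in donor macrophages. Of the 17 MHC class I genes 2 rose, H2-D1 (values of 3525 ± 279.9 against 1558 ± 302, SD, adjusted p = 0.0134) and Nlrc5, the class I transactivator (1.38 ± 0.19), and 13 rose adjusted over the list alone (median 0.97, camera adjusted p = 6.18e-24, and 0.0345 with an estimated correlation). Of the 17, H2-Q4 and H2-Q6 were low in TCD host library 1 alone (3.54 against at least 24.8 and 9.93 against at least 42.9 in the other host libraries). In the interferon-gamma list 1 of 19 rose, Gbp8 (2.74 ± 0.24), and 15 rose adjusted over the list alone (median 1.37; camera adjusted p = 3.18e-22, but adjusted p = 0.0661 with an estimated correlation). Cxcl9, a chemokine that draws activated T cells, had values of 51.3 ± 33.2 against 5.70 ± 4.63 and did not pass over all genes (adjusted p = 0.141). Complement genes were called with either correlation (median 0.22, camera adjusted p = 1.82e-06, and 0.0156 with an estimated correlation), with 6 of 14 rising adjusted over the list alone, such as C4b at 2.04 ± 0.48 and C2 at 1.21 ± 0.30. H2-M2 (1.89 ± 0.29), Aldh1l1, a folate enzyme used as an astrocyte marker (1.77 ± 0.22), and Spock1, a matrix proteoglycan (1.41 ± 0.18), also rose, whereas Thbs2, a thrombospondin (-1.67 ± 0.23), and Serpinf1 (-0.92 ± 0.15) fell. H2-M2, Aldh1l1 and Spock1 had mean values of at most 6.89.

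**Figure D2:**
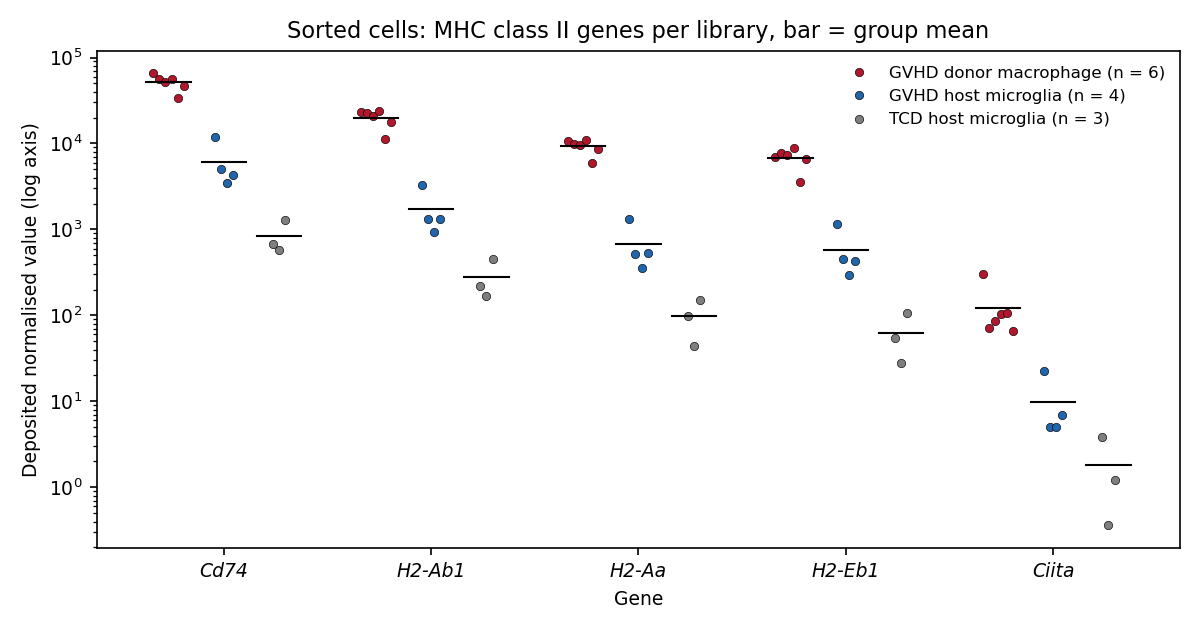
Deposited normalised value (log axis) of 5 MHC class II genes in each sorted library, with a bar at each group mean. For these genes the 4 GVHD host libraries sat between the 3 TCD host and the 6 donor libraries, with no overlap.

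Other lists called upward had no member past the threshold over all genes except Aldh1l1, and their calls were lost with an estimated correlation. Type I interferon genes had a median of 0.45 with 3 of 26 rising adjusted over the list alone (adjusted p = 0.301 with an estimated correlation), and mitochondrially encoded RNA, which codes for subunits of the respiratory chain, of 0.36 with 6 of 13 (adjusted p = 0.125 with an estimated correlation, mt-Nd5 at 0.64 ± 0.17). Natural killer and cytotoxic genes (0.72, Klrk1 at 1.33), chemokines (0.40, Cxcl10 at 1.16), co-stimulation (0.32, Cd274 at 1.27) and T cell genes (0.34, Lck at 0.63) had adjusted p = 0.253, 0.301, 0.0978 and 0.462 with an estimated correlation. Astrocyte (0.46), reactive astrocyte (0.46, Cp at 1.30 with 10.6 in TCD host library 1 against at least 59.5 in the other host libraries) and oxidative phosphorylation genes (0.14, Ndufa1 at 0.42) had 0.125, 0.0661 and 0.607. Proliferation (-0.40, Bub1 at -0.70), homeostatic microglia (-0.16, P2ry12 at -0.29 ± 0.17) and neutrophil genes (-0.78, Ngp at -1.95 ± 1.41) were called downward, at adjusted p = 0.489, 0.533 and 0.556 with an estimated correlation. Ngp had 60.0 in TCD host library 1 against at most 9.48 in the other host libraries, and without that library 1 list was called downward and the homeostatic microglia list had a median of 0.05 (adjusted p = 0.756). Neither brain-engrafted macrophage genes (-0.02, Ms4a7 at 0.23 ± 0.38, Clec12a at 0.50 ± 0.33, Apoe at 0.59 ± 0.26), disease-associated microglia genes (0.02) nor glucocorticoid-responsive genes (-0.11) were called. Tmem119 (-0.16 ± 0.21) and Sall1 (-0.16 ± 0.36) did not pass the test.

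TCD host library 1 stood apart from the other host libraries, with 121 genes at least 4-fold higher and 43 at least 4-fold lower than in any of them, against at most 5 and 4 such genes in another host library. Without it limma called 11 genes, of which 8 were among the 14, and Cd74 kept a log2 fold change of 2.43 (adjusted p = 0.0484, with 0.00120 to 0.178 over all alternatives). Without it the MHC class II list had a median of 1.38 with 9 of 10 rising adjusted over the list alone and 2 over all genes, and the MHC class I list had 0.67 with 11 of 17 and 4. Both were called by camera (adjusted p = 1.92e-19 and 4.41e-24) but not with an estimated correlation (adjusted p = 0.0580 and 0.0513), where the complement list kept 0.0437. The count was 6 without GVHD host library 1, 2 or 4, 28 without GVHD host library 3, 7 without TCD host library 2, 21 without TCD host library 3, 1 among the libraries of the higher API number alone, 0 in a fit on these groups only (978 at an unadjusted p under 0.05) and 2 with the replicate number as a block.

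**Figure D3:**
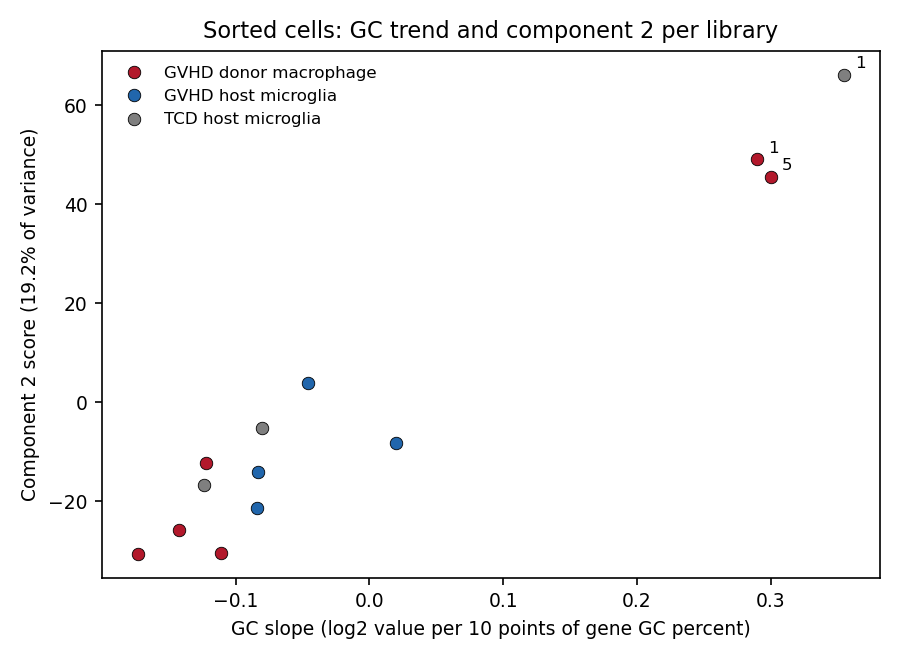
Slope of the log2 value on gene GC content (per 10 percentage points) against the score on the component of variance ranked 2 (19.2% of variance) for each sorted library. TCD host library 1 and donor libraries 1 and 5 had slopes of 0.355, 0.290 and 0.301, apart from the other 10 libraries.

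Donor macrophages were also set against host microglia of TCD mice, the resident cells of brains without GVHD. The donor cells had far higher macrophage and MHC class II values and lower microglial ones. Camera also called the interferon-gamma and MHC class I lists upward, with adjusted p = 0.384 and 0.340 with an estimated correlation. H2-Aa stood at 9237 ± 1854 against 97.9 ± 53.6 (SD, n = 6 donor and 3 TCD host libraries), a log2 fold change of 6.80 ± 0.36 (SE), and P2ry12 at 1159 ± 281 against 15545 ± 3002 (-3.85 ± 0.16). Limma called 2408 genes higher and 2437 lower, 1196 and 1013 of them by at least 2-fold. The comparison shares its donor libraries with the preceding donor comparison, so the results are not independent.

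Of the 10 MHC class II genes 8 rose and none fell (median 4.13; camera adjusted p = 4.81e-07, but adjusted p = 0.340 with an estimated correlation), led by H2-Eb1 (6.98 ± 0.42), H2-Ab1 (6.32 ± 0.37), Cd74 (6.09 ± 0.33) and Ciita (5.72 ± 0.20). MHC class I genes rose in 14 of 17 cases (median 1.40; camera adjusted p = 1.22e-06, but adjusted p = 0.340 with an estimated correlation), with Nlrc5 at 2.58 ± 0.18 and H2-D1 at 1.52 ± 0.16. Interferon-gamma response genes rose in 13 of 19 (median 1.68; adjusted p = 0.384 with an estimated correlation). Type I interferon genes rose in 21 of 26 (median 1.17; adjusted p = 0.384 with an estimated correlation). Chemokine genes rose in 12 of 19 cases with 1 fall (median 1.53; adjusted p = 0.384 with an estimated correlation), including Ccl8 (6.18 ± 0.82), Ccl7 (3.38 ± 0.33) and Cxcl16 (2.54 ± 0.14). Brain-engrafted macrophage genes rose in 18 of 20 (4.30, adjusted p = 0.0560 with an estimated correlation), monocyte genes in 15 of 15 (3.88, 0.340), lipid handling genes in 12 of 16 (1.13, 0.0560; Cd36, a fatty acid transporter, at 5.15 ± 0.37) and cholesterol synthesis genes in 5 of 15 (0.43, 0.643).

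The largest rises further included Plbd1 (7.24 ± 0.42), Klra2 (6.81 ± 0.41), Sirpb1c (6.60 ± 0.46), Clec12a (6.18 ± 0.31) and Gdf3 (6.08 ± 0.41). Homeostatic microglia genes fell in 18 of 20 cases (median -2.72; camera adjusted p = 3.91e-15, but adjusted p = 0.0560 with an estimated correlation). The largest falls were those of Upk1b, Adamts1, Slc2a5, Csmd3, Nav3, Ecscr, Sall1, Mlxipl, Jam2 and Adgrg1, from -5.68 to -4.74. The p53 targets fell in 11 of 14 cases with 1 rise (median -0.65; camera adjusted p = 0.00228, but adjusted p = 0.385 with an estimated correlation), among them Phlda3 (-3.13 ± 0.38) and Mdm2, the ubiquitin ligase that degrades p53 (-0.67 ± 0.15). Proliferation genes fell in 8 of 20 (median -0.92; camera adjusted p = 0.0145, but adjusted p = 0.678 with an estimated correlation), such as Stmn1 (values of 16.4 ± 4.69 against 36.7 ± 4.42, SD). The disease-associated microglia list had 11 rises and 4 falls (0.91, adjusted p = 0.263 with an estimated correlation, Lgals3, galectin 3, at 4.07 ± 0.33). Reactive astrocyte genes had 7 rises of 10 (1.74, adjusted p = 0.0560 with an estimated correlation, Vim at 3.59 ± 0.37). T cell (0.29) and glucocorticoid-responsive genes (-0.54) were not called, with Tmem119 at -1.87 ± 0.20, Ms4a7 at 5.58 ± 0.35 and Apoe at 4.83 ± 0.25. Groups did not overlap for 29.5% of tested genes, where chance gives 2.38%. Camera called 11 lists upward and 3 downward, none with an estimated correlation. With the title number as a replicate block 4482 genes were called, although donor and TCD host libraries come from different mice.

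**Figure D4:**
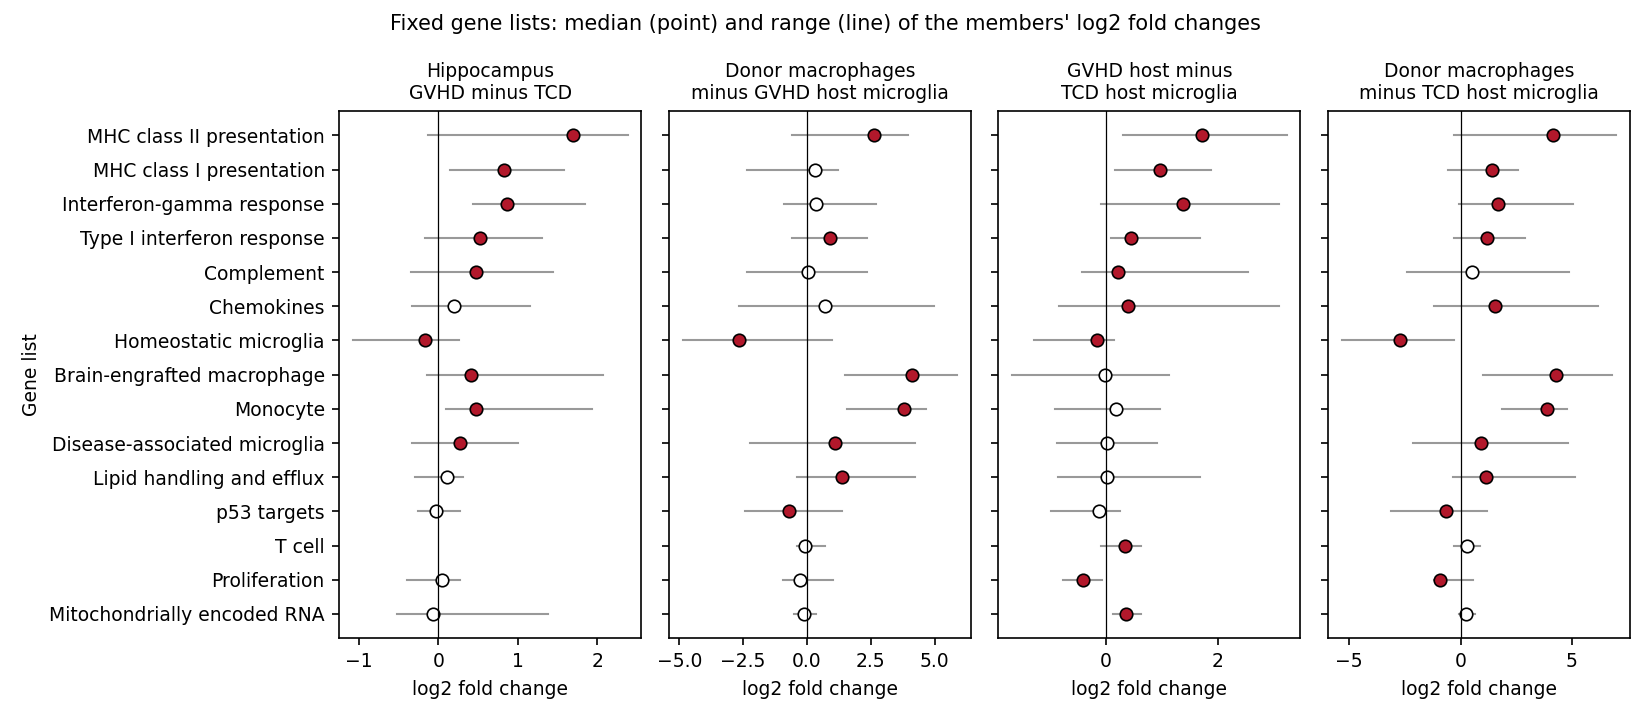
Median (point) and full range (line) of the members' log2 fold changes for 15 fixed gene lists in the 4 comparisons, with filled points where the camera adjusted p was under 0.05. MHC class II genes had medians of 1.70, 2.63, 1.72 and 4.13, from the left panel to the right.

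To ask whether the genes that mark donor macrophages were also higher in GVHD hippocampus, sets were taken from the sorted libraries and tested in the hippocampus libraries, which come from other mice. The 100 genes with the largest fold change higher in donor macrophages than in GVHD host microglia had a median log2 fold change of 0.23 in GVHD against TCD hippocampus, with 76 positive and 2 called higher (camera adjusted p = 9.47e-09, but adjusted p = 0.0652 with an estimated correlation). The 100 genes with the largest fold change the other way had a median of -0.02 (camera adjusted p = 0.825). The 11 tested genes higher in GVHD than TCD host microglia, among them H2-Eb1 and Cd74, had a median of 1.02 with 9 positive (camera adjusted p = 5.24e-05, but adjusted p = 0.259 with an estimated correlation). GVHD hippocampus also had the higher choroid plexus values, which moved together with these sets between the groups.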

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

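The counts of other splits of the libraries were planned before the data were examined. The restriction of splits by API number and all other tests in this part were chosen after the results were seen.

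In the hippocampus, the real grouping called 69 genes and the highest of the other 9 splits of the 6 libraries called 2; 10 splits are too few for a share under 0.05, and 1 of them, the real one, reached the real count. For donor macrophages against GVHD host microglia 1 of 100 splits drawn from 210, the real one, called as many as 5052 genes and the highest other called 1. This argues against chance as the source of that count if the libraries do not pair by animal, which the labels do not state. For GVHD against TCD host microglia 1 of 35 splits, the real one, called 14 genes or more and the highest other called 2. The bound set beforehand, fewer than 1 in 20 splits, left out that the model holds the API number fixed, and only 20 splits keep its balance, too few for a share under 0.05. For donor macrophages against TCD host microglia 1 of 84 splits, the real one, called 4845 genes or more, but the highest other called 1467. That split set donor libraries 1 and 5 and TCD host library 1 against the rest, the 3 libraries with a steep GC trend, and so points to a structure of the samples; without those 3 libraries 5429 genes were called. Donor and GVHD host libraries share API and description numbers, and donor and TCD host libraries, from different mice, share title numbers. Among the splits drawn, 8 and 7 others parted all libraries with shared numbers as the real one does, too few for a share under 0.05. They called at most 0 genes by limma, against 5052 and 4845.

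Choroid plexus and interferon genes were both higher in GVHD hippocampus, and a GC trend between libraries is argued against as the source of the choroid pattern, since Ttr kept a log2 fold change of 6.61 ± 0.70 (SE, adjusted p = 0.0222) once the trend was removed, with 0.00170 to 0.0994 over all alternatives. Tissue carried over with the hippocampus should raise all choroid genes in 1 ratio between libraries, and the log2 ratio of the excess in GVHD library 2 to that in libraries 1 and 3 ran over a range of 1.05 for 10 genes (-2.11 to -1.06). This exceeded the bound of 1 first set, by which carry-over would have been excluded. The condition that the range without its most extreme gene, Prlr, also reach 1 was added only after the value was known, and that range was 0.60, so carry-over and a change in choroid plexus expression cannot be told apart. For the interferon and MHC genes that passed over their lists alone, the same ratio had a median of -0.25 (quartiles -0.60 and 0.40), with 43 of 48 genes above the highest choroid ratio. The genes were chosen by their p in these same libraries, which favours genes alike in the GVHD libraries. The choice took 17 of 18 interferon-gamma, 14 of 17 MHC class I, 6 of 8 MHC class II and 11 of 20 type I interferon genes. Within that limit, the ratio argues against choroid tissue that carried the chosen genes at 1 fixed level in each mouse. Choroid tissue with a level that differed between mice cannot be excluded by this ratio. Of the genes called over all genes, Tgtp1 had a ratio of -1.14, within the choroid range, and Gbp9 of -0.16.

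MHC class II genes were higher in GVHD than TCD host microglia. Donor macrophages in the host gate would bring their other abundant transcripts too, but 59 donor-specific genes gave a median donor share of 0.677% (quartiles 0.149% and 1.83%) where H2-Aa, H2-Ab1, H2-Eb1 and Cd74 would need 6.42% to 10.4%; 4 of the 59 genes, Cfb, Hpse, Pfkp and Cd36, reached such shares, and in GVHD host library 1 the median share was 3.22% against at least 13.5%. Against TCD host libraries 2 and 3 alone the share was 1.57% (quartiles 0.735% and 2.59%) where 6.42% to 10.3% would be needed. TCD host library 1 did not account for the difference, since the median log2 fold change of these 4 genes was 2.54 without that library (2.25 to 2.98, no overlap for any of the 4, where chance gives 13.3%). Removing the GC trend left a median of 2.86, and Cd74, at 2.82, had 2.83 after median-of-ratios rescaling and 2.86 by quantile normalisation, and a response of host microglia to GVHD stays open as a candidate explanation, a hypothesis found on the same data, as does the untested library preparation.

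TCD host library 1 stood apart from the other 6 host libraries, and its description field carries Syn where the other TCD host libraries have TCD. The 121 genes high in it alone had a median GC content of 58.6%, against 49.2% over all tested genes, and were higher in donor libraries 1 and 5 than in the other 4 donor libraries by a median of 2.28 on the log2 scale, consistent with a GC trend shared by these 3 libraries for most of them. Of the 121 genes 12 had a difference under 1, among them markers of macrophages at the borders of the brain, Cd163 (21.7 against at most 2.35 in the other hosts, difference -1.21), Lyve1 (9.52 against 0.785, -1.12) and F13a1 (146 against 13.5, -1.53), so another cell type in that library stays open for these genes and was not tested. The 43 genes low in it alone had a median GC content of 49.7%. Their median difference between the same donor libraries was -0.56 (quartiles -0.93 and -0.11), so as a set they did not follow the GC trend. Single genes ran from -2.08 (Gm26825) to 1.37 (Ctse), with Ccr6 at -1.67, so a shared trend stays open for some. For donor-type cells as their cause, dilution to a value 4-fold lower would need most of the library to be such cells. The median share was 0.843% (upper quartile 2.91%), from genes chosen as low in TCD host libraries, this library included. Ms4a7, Clec12a and Apoe, fixed beforehand, had means of 21.9, 3.73 and 2606 in TCD host and 865, 308 and 69531 in donor libraries. These values argue against donor-type cells. Of the 43 genes 20.9% (9 genes, Ccr6 among them, named after its values were seen) were also 4-fold lower in all 6 donor libraries, against 1.27% of 8890 genes at that level (1-sided exact binomial p = 3.31e-09, genes not being independent), so a mouse of another genotype than the other hosts is a candidate explanation that no sequence was used here to test. The 43 genes also held H2-Q1, H2-Q4, H2-Q6 and H2-Ea-ps on chromosome 17. A difference of genotype, if present, could therefore also enter the MHC values of this library, and results without it are given above.

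Some values in single libraries lay far from the rest of their group; 6 of 46 values tested did so, where chance gives about 1 in 20. In donor macrophages, library 1 had a Ciita value of 301 against 65.1 to 107 in the others, and a mean log2 value of 2.44 over the T cell genes against 0.46 to 1.12. In GVHD host microglia, library 1 had an H2-Ab1 value of 3294 against 934 to 1332, a Ciita value of 22.4 against 4.97 to 6.92, a mean log2 value of 5.03 over the brain-engrafted macrophage genes against 4.32 to 4.41, and a total of 890564.5 against 958416.9 to 961739.8. Spock1 differed in direction between tissues, with a log2 difference of -0.33 in GVHD against TCD hippocampus and a log2 fold change of 1.41 in GVHD against TCD host microglia; the groups did not overlap in either tissue, and the difference itself was not tested (1 of 29 results compared).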

How the results depend on the processing

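The GC correction, the Ttr covariate and the fit without the 3 sorted libraries with the steepest GC trend were chosen only after the results were seen. The other settings were planned, with the filter at 5 settled once the library totals were seen. The single-gene results covered only named genes called in the main fit, so none could gain a call and a reversal was unlikely. None of them reversed (4063 kept their direction and their side of the threshold and 297 lost the call). Of 889 list values the direction of the test reversed in 24, 64 lost the call and 14 gained one. The sign of the list median changed in 36 values, in 19 of them with the direction of the test kept, and in 7 the test reversed with the sign of the median kept. In hippocampus, 69 genes became 34 with a pseudocount of 8, 39 by quantile normalisation, 0 with no variance trend (2343 at an unadjusted p under 0.05), 43 at an absolute log2 fold change of at least 1, 16 with the replicate number as a block, 33 after GC correction. It ran from 0 (without GVHD 3 or TCD 2) to 123 (without TCD 3) when single libraries were left out, for a cause that was not tested. With Ttr as a covariate, which separates the groups, 96 genes were called, only 1 of them among the 69. The share of rises, 66.7%, became 45.8% with the Ttr covariate and 48.0% without TCD 3, where falls outnumbered rises, 76.9% by quantile normalisation, 90.9% after GC correction, 93.8% with the replicate block and 93.9% without GVHD 2. List calls, 20, became 13 by quantile normalisation, all upward, 5 with Ttr as a covariate (1 up, 4 down) and 0 with an estimated correlation. Directional fry called 0 lists and mixed fry, which gives no direction, called 20. The MHC class II list lost its call with the Ttr covariate (median 1.48) and, at 1.70, with an estimated correlation and by both kinds of fry. With the Ttr covariate the medians of MHC class I (-0.0239), interferon-gamma (-0.310), type I interferon (-0.0894), disease-associated microglia (-0.220), neurogenesis (0.111) and glucocorticoid genes (-0.205) reversed. The test of the glucocorticoid list (median 0.00831) also reversed with a filter at 5 (-0.0198) and without GVHD 3 (-0.0350) or TCD 3 (-0.0409), and with no filter at an unchanged median (0.00831). Its median alone changed sign with a pseudocount of 8 (-0.00537) and without TCD 1 (-0.0160), and the highest without a single library was 0.0196 (without TCD 2).

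Donor macrophages against GVHD host microglia gave 4099 to 5900 genes over the other settings, 5815 with the animal block, and 2133 at an absolute log2 fold change of at least 1. List calls, 10, became 0 with an estimated correlation, where MHC class II lost its call at 2.63, 21 by directional and 36 by mixed fry. The test of the T cell genes (median -0.0801) reversed, with its median changing sign, at a pseudocount of 8 (0.00390), with the replicate block (0.0446) and without donor 5 (0.00674) or GVHD host 2 (0.0119). It reversed with the sign of the median kept by quantile normalisation (-0.112) and without donor 6 (-0.0213) or GVHD host 3 (-0.0356). With array weights only the median changed sign (0.00468), and the lowest without a single library was -0.221 (without donor 1). GVHD against TCD host microglia went from 14 genes to 2 with the replicate block, 1 in libraries of the higher API number, 0 in a fit on the compared groups only (978 unadjusted) and 28 with array weights. Without single libraries it ran from 6 (without GVHD host 1, 2 or 4) to 28 (without GVHD host 3). List calls, 16, became 3 with an estimated correlation, 5 by directional and 8 by mixed fry. The test of the brain-engrafted macrophage genes (median -0.0180) reversed, with its median changing sign, by quantile normalisation (0.0272), without the API covariate (0.0128) and without TCD host 3 (0.0921). It reversed with the sign kept by directional fry (-0.0180) and without GVHD host 1 (-0.112) or TCD host 2 (-0.180). Only the median changed sign in 6 other settings, from 0.0397 (replicate block) to 0.249 (without TCD host 1). The test of the disease-associated microglia genes (median 0.0154, highest 0.119 without TCD host 1) reversed without TCD host 2 (-0.0738), and their median alone changed sign with a pseudocount of 8 (-0.00634), without GVHD host 2 (-0.00902), GVHD host 4 (-0.00303) or TCD host 3 (-0.00238) and in a fit on the compared groups only (-0.0126). The homeostatic microglia median, -0.159, changed sign without TCD host 1 (0.0452), in libraries of the higher API number (0.00841) and without the 3 libraries with the steepest GC trend (0.00841), each time with the call lost. Leaving out those 3 libraries left GVHD host 1 as the only library of the lower API number, so the API covariate absorbed it. The last 2 fits therefore gave the same estimate for this comparison. Donor macrophages against TCD host microglia gave 3740 to 5800 genes, and 2209 at an absolute log2 fold change of at least 1. List calls, 14, became 0 with an estimated correlation, where MHC class II lost its call at 4.13, 24 by directional and 37 by mixed fry. The T cell median, 0.292, changed sign without TCD host 1 (-0.00417) and in libraries of the higher API number (-0.0311). In hippocampus the donor-higher set (0.23) and the GVHD-host-higher set (1.02) lost their calls with an estimated correlation, and with single libraries left out the donor-lower set ran from -0.0375 (without GVHD 3) to 0.00908 (without GVHD 2, its test reversed as well), with only its test reversed without TCD 2 (-0.0219). The count test was not run because whole counts could not be recovered, and depth limits low values most in TCD host library 3 (7901523 reads).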

Other observations

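The values in this part were chosen after the results were seen. Donor macrophages and GVHD host microglia differed in which sensors and mediators of inflammation they expressed, with members of the same fixed lists going both ways (n = 6 and 4, adjusted by limma over all genes). Among Toll-like and pattern recognition receptors 6 of 17 rose and 6 fell: beside Tlr8, the scavenger receptor Msr1 (log2 fold change 3.87 ± 0.23, SE) and Clec7a, a receptor for fungal glucan (2.49 ± 0.28), rose, and Tlr3, which senses double-stranded RNA, fell (-2.33 ± 0.12), as did Tlr9, which senses DNA (-1.42 ± 0.22). Among 11 inflammatory cytokines 4 rose, including Il10 (3.40 ± 0.28) and Il1b (2.15 ± 0.28), and 4 fell, including Il6 (-2.14 ± 0.25), Csf1 (-2.09 ± 0.27) and Tnf (-1.95 ± 0.28). Complement genes rose in 6 of 14 cases and fell in 3, with Cfb (2.34 ± 0.61) and C3 (1.98 ± 0.40) up. In the dendritic cell list 7 of 12 rose and 3 fell, with Cd209a (4.26 ± 0.91) and Flt3, a growth factor receptor (2.33 ± 0.22), up and Fscn1, an actin-bundling protein that microglia also made (267 ± 83.6 in host cells), down (-3.20 ± 0.41). Of the iron and oxidative stress genes 6 of 16 rose and 3 fell: the ferritin chains Fth1 (1.28 ± 0.13) and Ftl1 (1.05 ± 0.12) and Hmox1, which degrades heme (1.04 ± 0.15), rose, whereas the iron exporter Slc40a1 (-2.50 ± 0.18) and the transferrin receptor Tfrc (-1.20 ± 0.18) fell. None of these 5 lists was called by camera, and mixed fry called each.

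In the hippocampus, further called genes outside the lists were Enpp2, the enzyme autotaxin (2.74 ± 0.33, SE, n = 3 and 3), Trim56 (0.72 ± 0.09), Fgl2 (1.24 ± 0.19) and Gas6, a ligand of the receptor Axl (0.49 ± 0.08). Enpp2 had its lowest GVHD value in library 2 (572, against 1367 and 1615), as Ttr did, whereas Fgl2 had its highest there (13.9, against 10.7 and 8.39). Of the mitochondrially encoded genes mt-Atp8 rose (1.38 ± 0.14), with a list median of -0.07. In sorted cells, Igkc, an antibody light chain, had a value of 208 in donor library 1 and 15.1 in TCD host library 1, and at most 1.71 in the others, and Hba-a1, a hemoglobin chain, had 32.5 in donor library 2.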
